A study of Mus musculus with 10 samples.

How the data were processed

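The series holds 10 bulk RNA libraries of sorted thymic epithelial cells (TEC) of the mouse. Per the labels, thymi were digested with Liberase TH and DNase, the cells were sorted, RNA was isolated with Dynabeads, and libraries were built by MARS-seq, which counts the 3′ ends of transcripts. The markers used in the sort are not given in the sources used here. The labels assign 3 libraries to a Foxn1 mutant they call del AR3 (AR3_mut), 3 to its heterozygous control (AR3_het) and 4 to nu/nu mice (nude). AR3_mut and AR3_het are labelled C57BL/6 and 4.5 weeks of age, and nude is labelled ICR and 5 weeks of age. Strain and age therefore change together with the nude genotype. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

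Counts were deposited as 1 table of raw counts per gene, with 15790 genes and 10 columns of whole numbers, per the file headers. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the mm10 build, without their roles or order. Whether molecular identifiers were collapsed is not given in the sources used here, so counting intervals and floors cover counting error only. The highest count of every gene in the table was 6 or more, and 0 mitochondrially encoded genes were listed. Of the gene symbols, 15241 matched gene names of GENCODE M21. A further 20 columns of normalized or transformed values per library were not used. The same table carries the authors' log2 fold changes and adjusted p-values for 3 comparisons, per the file headers. The authors' comparison names use Het, nude and Foxn1_ATAC. The last name is not in the labels and was taken as AR3_mut because Het and nude name the other groups. Across genes, the authors' deposited log2 fold changes correlated with those computed here at Pearson r = 0.997 for AR3_mut against AR3_het, 0.999 for nude against AR3_het and 0.988 for AR3_mut against nude.

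Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 12912 genes. Library sizes were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to all 10 libraries with group as the only term, so that the 3 groups shared 1 estimate of the spread. AR3_mut was tested against AR3_het, nude against AR3_het and AR3_mut against nude, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All tests were two-sided. The SE printed with a log2 fold change is its absolute value divided by the square root of the test's F statistic. For a gene with few counts in a group, this SE can be smaller than counting error alone. Unless stated otherwise, levels are CPM (edgeR's counts scaled to TMM-adjusted library size), as mean ± SD over the libraries of a group. A gene with 0 counts in every library of a group has no finite fold change, so its fold was computed from counts pooled over each group against a floor of 3 counts over the group and is given as a lower bound. For a gene with 1 to 3 counts in a group, the log2 ratio of CPM is given with a 95% counting interval. Depth ran from 1056066 counts in AR3_mut 3 to 4175851 counts in AR3_het 1. Scaled to these library totals without TMM, 3 counts correspond to between 0.718 CPM in AR3_het 1 and 2.84 CPM in AR3_mut 3.

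Before the data were examined, 35 gene lists were fixed from general knowledge of the thymus and of other cell types a sort could hold. Of these, 31 had at least 5 tested members and were compared with the other genes by camera, with the preset correlation of 0.01 between genes and adjustment over lists. The erythroid list had 3 tested members, the sex-linked list 1, the list of genes known to be defective in C57BL/6 2 and the mitochondrial list 0, so they are given as levels where measured. Some genes are in several lists. The lists cover cortical TEC, medullary TEC, post-Aire and cornified-like medullary TEC, tuft cells, progenitor-associated genes, airway-like ciliated and secretory cells, keratinocytes, thymocytes, B cells, myeloid cells, fibroblasts and pericytes, endothelium, adipocytes, parathyroid and thyroid, muscle, and neural cells. The other lists cover thymocyte-supporting factors, genes reported as Foxn1-dependent, MHC class I and class II presentation, early thymus transcription factors, cell cycle, immediate-early and dissociation stress, interferon, NF-kB, Notch, Wnt and BMP, extracellular matrix, tight junctions and Aire-dependent antigens.

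Named genes follow a rule also fixed before the data were examined. The rule takes Foxn1, then the 8 largest fitted fold changes in each direction among genes that passed the test, reached 20 CPM in the higher group and did not overlap between groups. Predicted gene models, ribosomal protein genes and antigen receptor segments were passed over there. Some genes that the rule names are not reported here. From each list it takes up to 4 members with the smallest adjusted p, or up to 2 of the most abundant where no member passed. Members that went against their list's direction, and Dll4, Epcam, Krt8 and Krt18 against AR3_het, were named after their values were seen. Genes of multigene families, such as the secretoglobins, major urinary proteins, classical and non-classical H2 genes and the Ifi200, Gbp, Rnaset2 and C1r or C1s families, are uncertain where the authors' counting could split reads between copies.

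The tests were first run on simulated counts with 200 changed genes, drawn only from the more abundant genes. Recovery of scarcer genes was therefore not measured. For AR3_mut against AR3_het, 81% of genes changed 4-fold and 22% of genes changed 2-fold were recovered among 12221 genes. The corresponding shares were 93% and 31% among 12265 genes for nude against AR3_het and 78% and 19% among 12228 genes for AR3_mut against nude. False calls made up 5.5%, 2.36% and 7.62% of the calls. Both comparisons with AR3_het share the same controls, so their correlation and overlap were also computed in 20 simulated data sets without any effect.

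Alternatives fixed before the data were examined were DESeq2 size factors, DESeq2 1.42.0, limma-voom with and without library quality weights (limma 3.58.1), no filter and a stricter filter of 20 counts in 3 libraries, fits of the 2 groups alone, the replicate number as a block, thinning to the smallest library, a test against a 1.5-fold change, an estimated correlation and fry for the lists, and each library left out in turn. Library totals without TMM, the joint removal of AR3_mut 3 and nude 1, and the removal of genes above 0.5% of a library were added after seeing the data.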

Results

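Bulk MARS-seq profiles of sorted TEC, the epithelial cells of the thymic stroma, were compared between mice with a Foxn1 mutation called del AR3, their heterozygous controls and nu/nu mice. Foxn1 encodes a forkhead transcription factor that TEC need to differentiate, and nu is a loss-of-function mutation of it. AR3_mut and AR3_het each had 3 libraries from C57BL/6 mice of 4.5 weeks, and nude had 4 libraries from ICR mice of 5 weeks. AR3_mut 1, 2 and 3 held 2667973, 1785283 and 1056066 counts. AR3_het 1, 2 and 3 held 4175851, 2948283 and 3732671, and nude 1 to 4 held 3302161, 2587840, 1901282 and 2709115. Every pair of libraries within a group differed by more than counting error, with a chi-square per degree of freedom of 4.29 or more, so no library was a copy of another. In nude 1, Scgb1b27 alone took 4.08% of the counts and the 10 most abundant genes took 16.7%, and in nude 3 Tg took 1.68%. Per-library levels of Ddx3y, Xist, H2-Ea-ps and Nnt are given here as CPM of library totals without TMM. The Y-linked gene Ddx3y reached 104 CPM in AR3_het 3 and 1.2 CPM or less in the other 9 libraries. Xist was 1.34 CPM in AR3_het 3 and at least 25.6 CPM elsewhere. H2-Ea-ps, which is defective in C57BL/6, was at 3.63 to 28.8 CPM in the nude libraries without TMM. It was at 0 to 1.12 CPM in the libraries labelled C57BL/6. With TMM, its means were 13.7 ± 12.5 CPM in nude and 0.584 ± 0.587 CPM in AR3_mut, with 0 counts in AR3_het. Without TMM, Nnt, the other measured gene of that kind, did not separate nude from the other libraries. It was at 57.8 to 72.3 CPM in nude and 32.2 to 67.8 CPM in the others. With TMM, the Nnt means were 72.1 ± 4.07 CPM in nude, 52 ± 18.1 CPM in AR3_mut and 34.6 ± 2.12 CPM in AR3_het.

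Libraries separated by group. The first principal component held 68.3% of the variance and parted AR3_het from the other groups. The second held 12.7% and parted AR3_mut from nude, which also differ in strain and age. Across genes, the correlation of log2 CPM was 0.918 to 0.98 within groups, 0.854 to 0.92 between AR3_mut and nude, 0.59 to 0.673 between AR3_mut and AR3_het and 0.599 to 0.638 between AR3_het and nude. Genes are not independent replicates in these correlations.

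Foxn1 was read first, as the gene named in the labels. The gene (ENSMUSG00000002057.4) lies on chromosome 11 from 78357577 to 78386558 on the minus strand of GRCm38. It had 4, 2 and 2 counts in AR3_mut 1 to 3, 1844, 1046 and 1711 counts in AR3_het 1 to 3, and 4, 3, 1 and 2 counts in nude 1 to 4. The means were 1.57 ± 0.417 CPM in AR3_mut (SD, n = 3), 355 ± 33.8 CPM in AR3_het (SD, n = 3) and 1.01 ± 0.403 CPM in nude (SD, n = 4). By edgeR's quasi-likelihood test, Foxn1 was lower than in AR3_het in AR3_mut (log2 fold change −7.83, SE 0.27, adjusted p = 3.26e-08) and in nude (−8.34, SE 0.24, adjusted p = 6.4e-09). At so few counts in AR3_mut and nude, these SEs are smaller than counting error alone would give. The difference between AR3_mut and nude was 0.51 (SE 0.41, adjusted p = 0.685) and was not detectable at this depth. In the authors' deposited table the log2 fold changes of Foxn1 against AR3_het were −7.93 and −8.44. The sources used here do not say where AR3 lies relative to the counted 3′ end, and the nu mutation need not remove the transcript, so these counts describe the groups and do not check the deletion itself.

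**Figure D1:**
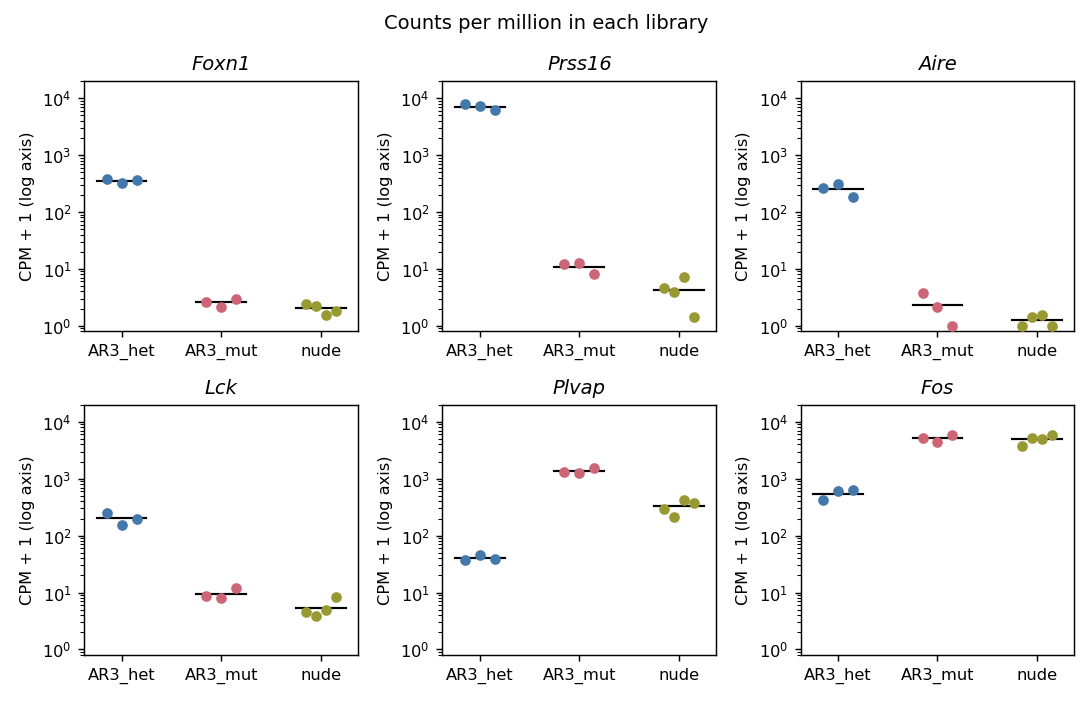
CPM plus 1 on a log axis for 6 genes in each library, with a black bar at the group mean and the 3 groups on the x axis. Foxn1, Prss16, Aire and Lck lie highest in the 3 AR3_het libraries, and Plvap and Fos lie lowest there.

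The comparison of AR3_mut with AR3_het shows what differed at the same strain and age label, although AR3_het 3 reads as male and the AR3_mut libraries as female. Most genes that mark cortical TEC fell in AR3_mut. Prss16, a thymus-specific serine protease, fell from 7073 ± 790 CPM to 9.96 ± 2.6 CPM (SD, n = 3 and 3), a log2 fold change of −9.43 (SE 0.56, adjusted p = 6.24e-07). Tbata, a gene of thymus and brain, fell from 5561 ± 888 CPM to 8.81 ± 3.21 CPM (−9.24, SE 0.41, adjusted p = 1.33e-07), and Ccl25, a chemokine that draws progenitors into the thymus, fell from 4050 ± 626 CPM to 11.3 ± 4.15 CPM (−8.43, SE 0.37, adjusted p = 1.33e-07). Psmb11, the thymoproteasome subunit of cortical TEC, had 1 count over the AR3_mut libraries against 216 ± 6.01 CPM in AR3_het, a log2 ratio of −10.15 (95% counting interval −15.46 to −7.67). Of 18 cortical TEC genes, 13 fell and 3 rose, and the counts were the same when adjusted over the list alone (median −1.80, camera adjusted p = 2.15e-07). The 3 that rose were Bmp4, Kitl and Slco3a1. Genes reported as Foxn1-dependent fell in 15 of 22 cases and 1 rose (16 and 1 adjusted over the list alone, median −2.91, adjusted p = 1.2e-11). Dll4, the Notch ligand that cortical TEC present to thymocytes and that endothelial cells also express, stood at 163 ± 32.8 CPM in AR3_mut and 127 CPM in AR3_het and did not pass the test (0.36, adjusted p = 0.445).

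Medullary genes fell with the cortical ones. Aire, the regulator that drives tissue-restricted antigens in medullary TEC, was at 1.3 ± 1.37 CPM against 252 ± 67.2 CPM (−7.22, SE 0.48, adjusted p = 8.95e-07). Fezf2, another regulator of such antigens, had 2 counts over the AR3_mut libraries against 259 ± 53.1 CPM, a log2 ratio of −9.39 (95% counting interval −12.43 to −7.53). Of 20 medullary TEC genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, median −3.50, adjusted p = 6.08e-10). Of 14 post-Aire and cornified-like genes 12 fell and 0 rose, also when adjusted over the list alone (median −5.19, adjusted p = 1.26e-12). They included Krt10, a keratin of differentiating epidermis (−5.02), and Krtdap (−8.54). Of 16 tuft cell genes 15 fell and 0 rose, also when adjusted over the list alone (median −6.63, adjusted p = 1.26e-15), with Avil at 3.92 CPM against 374 CPM (−6.65). Of 22 Aire-dependent antigens 18 fell and 2 rose, also when adjusted over the list alone (median −6.98, or −5.82 with genes at 0 at their bound, adjusted p = 1.26e-15). Apoa4 and Csn2, proteins of intestine and milk, had 2 and 1 counts over the AR3_mut libraries against 206 and 210 CPM in AR3_het. The 2 that rose were Spt1 and Mup5, genes of salivary gland and liver or gland secretions, and the call of Spt1 was lost in 6 of 15 alternatives. Of 16 keratinocyte genes 14 fell and 0 rose, also when adjusted over the list alone (median −4.71, or −3.69 at bounds, adjusted p = 8.79e-11).

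Antigen presentation by class II fell broadly. Of 16 genes of MHC class II presentation 15 fell and 0 rose (16 fell adjusted over the list alone, median −3.81, adjusted p = 1.44e-11). The list took 4.08 to 5.01% of the counts in AR3_het libraries and 0.139 to 0.33% in AR3_mut libraries. Cd83, a stabiliser of class II at the surface, fell from 435 ± 59.6 to 8.14 ± 6.65 CPM (−5.58, SE 0.49, adjusted p = 6.36e-06), and Ctsl, the protease of cortical class II processing, fell from 5453 to 762 CPM (−2.84). Of 17 class I genes 5 fell and 1 rose, also when adjusted over the list alone (median −0.33, adjusted p = 0.02). The 5 were the peptide transporter gene Tap1 (−0.83), the proteasome genes Psmb9 (from 569.8 to 142 CPM), Psmb10 (−1.90) and Psmb11, and the class I regulator Nlrc5 (−0.98), whose call was lost without AR3_mut 1, 2 or 3 and without AR3_het 1 or 2. The class I call was lost with an estimated correlation (adjusted p = 0.473) and without AR3_mut 1. Of 16 thymocyte-attracting and thymocyte-supporting genes 10 fell and 4 rose, also when adjusted over the list alone (median −1.42, adjusted p = 0.000132). The 4 that rose were Kitl, Bmp4, Icam1 and Tgfb2, which stromal cells other than epithelium also express, and the call of Tgfb2 was lost without AR3_mut 2 or AR3_het 3.

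Genes of thymocytes were almost absent from AR3_mut libraries. Of 26 thymocyte and T cell genes 25 fell and 1, Tmsb10, rose, also when adjusted over the list alone (median −6.56, or −5.75 at bounds, adjusted p = 4.58e-23). Cd8b1, the coreceptor chain of CD8 cells, had 0 counts in AR3_mut and was at least 435-fold lower than in AR3_het, where it reached 239 ± 69 CPM. Rag1, the recombinase of developing lymphocytes, also had 0 counts and was at least 235-fold lower. The list took 0.207 to 0.361% of the counts in AR3_het and 0.0348 to 0.0447% in AR3_mut. Of 18 myeloid genes 12 fell and 1, Csf1r, rose, also when adjusted over the list alone (median −2.32, adjusted p = 0.00127, lost with an estimated correlation at adjusted p = 0.333). The myeloid share of the counts was uneven, at 0.322, 0.0415 and 0.0196% in AR3_mut 1 to 3 against 0.101 to 0.179% in AR3_het.

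Genes of other stromal cells rose in AR3_mut. All 21 tested endothelial genes rose, also when adjusted over the list alone (median 5.26, adjusted p = 6.09e-31). Selp, an adhesion receptor of endothelium and platelets, went from 1.41 ± 0.304 to 498 ± 74.1 CPM (8.42, SE 0.29, adjusted p = 3.26e-08). Plvap, a protein of fenestrated endothelium, went from 39.8 ± 4.84 to 1352 ± 143 CPM (5.09, SE 0.28, adjusted p = 3.94e-07). The endothelial list took 0.034 to 0.0431% of the counts in AR3_het and 0.955 to 1.12% in AR3_mut. Of 25 fibroblast and pericyte genes 23 rose and 1, Thy1, which T cells also carry, fell, also when adjusted over the list alone (median 3.11, adjusted p = 1.6e-10). Sparc, a secreted matrix protein, rose from 206 ± 64.9 to 3262 ± 254 CPM (3.98), and the collagen gene Col3a1 rose from 26.8 to 818 CPM (4.92). Of 24 immediate-early and dissociation stress genes 23 rose and 0 fell (24 rose adjusted over the list alone, median 2.61, adjusted p = 3.63e-17). Among them Fos rose from 548 ± 114 to 5193 ± 689 CPM (3.24) and Atf3 from 152 to 3223 CPM (4.40). These immediate-early genes took 0.82 to 1.06% of the counts in AR3_het and 4.22 to 5.03% in AR3_mut. Epithelial genes were not gone. Epcam was at 151 ± 74.5 CPM in AR3_mut and 263 ± 71.4 CPM in AR3_het (−0.80, adjusted p = 0.122), and the simple-epithelium keratins Krt8 (−1.19, adjusted p = 0.0193) and Krt18 (−1.51, adjusted p = 0.00155) fell, with the call of Krt8 lost without AR3_mut 1 or AR3_het 2.

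Signalling and matrix genes also differed. Whether more endothelial and fibroblast RNA carries these differences, here or in nude below, was not tested. Of 28 Wnt and BMP genes 17 rose and 6 fell (18 and 6 adjusted over the list alone, median 1.09, adjusted p = 0.00313, lost with an estimated correlation at adjusted p = 0.1). Bmp4, a ligand of the pathway, rose from 3.16 ± 0.377 to 36.7 ± 1.86 CPM (3.50, SE 0.22, adjusted p = 7.14e-07), and its target genes Id1 (3.34) and Id3 (2.74) rose. Of 18 Notch pathway genes 11 rose and 2 fell, also when adjusted over the list alone (median 1.17, adjusted p = 0.0274). Notch3, a receptor of pericytes and smooth muscle among other cells, rose (3.56), as did the target Hes1 (1.89), while Hes6 fell (−3.41). The Notch call was lost with an estimated correlation (adjusted p = 0.473) and without AR3_mut 3. Of 20 extracellular matrix genes 10 rose and 3 fell (11 and 3 adjusted over the list alone, median 1.55, adjusted p = 0.00127), with Nid1, a basement membrane protein, rising from 7.0 to 129.9 CPM. Of 22 cell cycle genes 15 fell and 1, Pcna, rose (18 and 1 adjusted over the list alone, median −1.64, adjusted p = 0.00303, lost with an estimated correlation at adjusted p = 0.495). Lists of early thymus transcription factors (4 rose and 4 fell of 14, adjusted p = 0.393), progenitor-associated genes (6 and 4 of 20, adjusted p = 0.639), interferon response (10 and 5 of 29, adjusted p = 0.654), NF-kB signalling (3 and 6 of 19, adjusted p = 0.393), and tight junctions and adhesion (3 and 5 of 21, adjusted p = 0.241) were not called. Adjusted over the list alone these counts were 4 and 5, 6 and 4, 10 and 6, 3 and 7, and 3 and 5. The NF-kB list was called with fry. Among the transcription factors, Pax1, which acts in the pharyngeal pouch, fell (−3.30) and Tbx1 rose (3.93).

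Ranked by fitted fold change, the genes named for their increase in AR3_mut began with Scgb1b27. Scgb1b27, a secretoglobin, was at 5313 ± 4540 CPM against 1.06 ± 0.565 CPM (12.27, SE 2.75, adjusted p = 0.00611), Glycam1 at 3672 ± 2930 CPM (11.17), Prol1, a lacrimal and salivary proline-rich protein, at 1986 ± 2086 CPM (10.63) and Mup5 at 399.5 ± 252 CPM (10.14). Scgb2b27 was higher too (12.03), and Scgb2b26 had 0 counts in AR3_het and was at least 619-fold higher on counts pooled over each group. Scgb2b26 was uneven in AR3_mut, at 106.5 ± 139.8 CPM, so the SD exceeded the mean. The calls of Scgb1b27, Scgb2b27 and Glycam1 were lost with limma-voom. Selp and the cytokine gene Il6 (8.34) complete these 8 genes. Ranked by fitted fold change, the genes named for their decrease had 0 counts in AR3_mut, where a fitted fold is no measure of size, and their bounds are smaller than the falls of Prss16 and Tbata. They included Cd8b1, Rag1, the keratinocyte genes Calm4 and Rptn (at least 306-fold and at least 275-fold lower), the neuroendocrine gene Resp18 (at least 169-fold), Sh2d7 (at least 152-fold) and Slc6a7 (at least 146-fold).

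In all, 5402 of 12912 genes (41.8%) differed between AR3_mut and AR3_het, 2741 higher and 2661 lower in AR3_mut, and 4213 of them by 2-fold or more. With library totals in place of TMM, 2066 of 5947 called genes were higher in AR3_mut, so the balance of directions depends on the scaling. The authors' deposited table gave 5908 genes with an adjusted p under 0.05, and 5241 were shared with the 5402, all with the same sign. Of 31 lists 20 were called, and 14 with an estimated correlation.

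**Figure D2:**
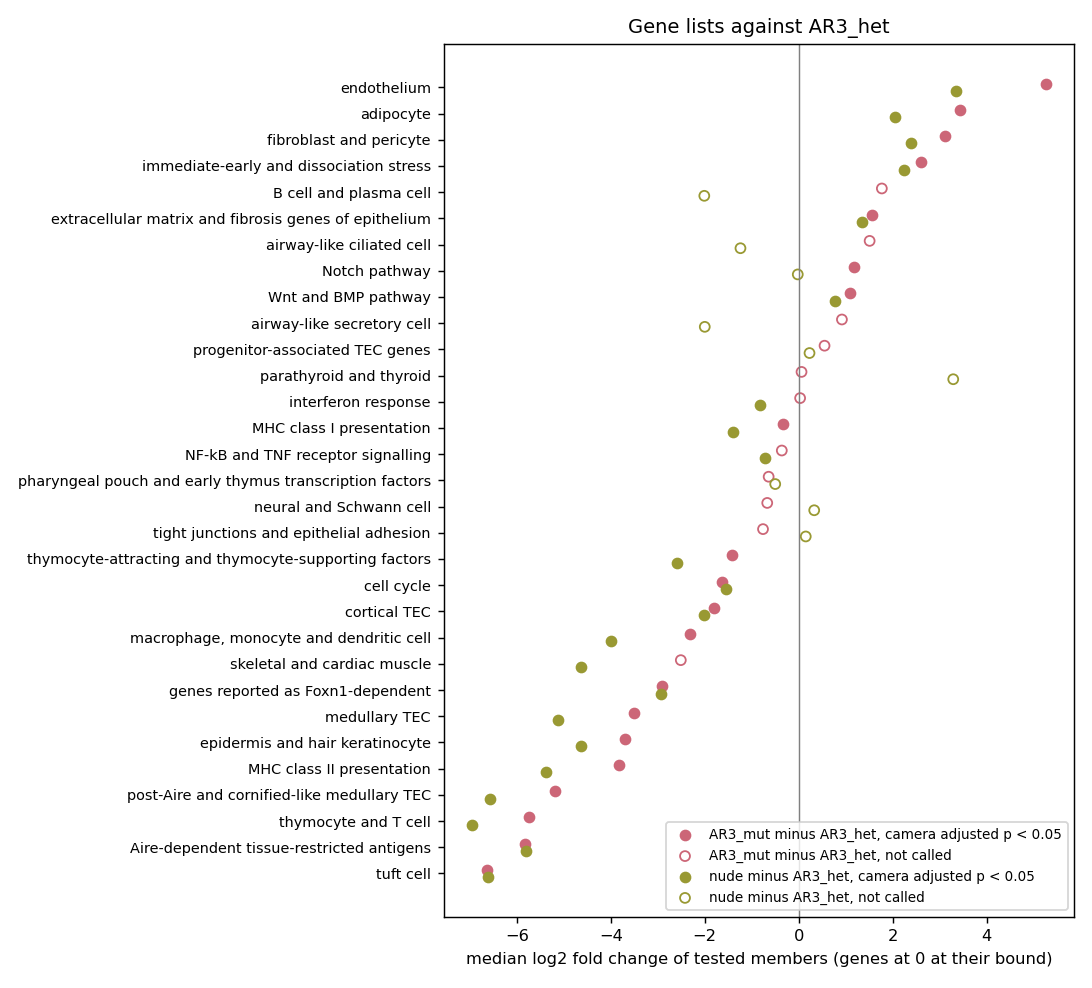
Median log2 fold change of the tested members of 31 gene lists on the x axis, AR3_mut in red and nude in olive, each against AR3_het; filled points passed camera and open points did not, and genes at 0 counts enter at their bound. Endothelial genes lie at 5.26 in AR3_mut and 3.34 in nude, and tuft cell genes lie below −6 in both, lowest of the lists in AR3_mut, while thymocyte genes are lowest in nude.

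The comparison of nude with AR3_het shows what differed with the nu/nu genotype, the ICR strain and 5 weeks of age together. Most cortical TEC genes fell in nude as well. Tbata fell from 5561 ± 888 to 0.421 ± 0.309 CPM (SD, n = 3 and 4; −13.54, SE 0.44, adjusted p = 1.03e-08). Prss16 (−11.12), Ccl25 (−10.27) and Spib, a transcription factor of medullary TEC (−6.71), fell too. Psmb11 and Fezf2 had 0 counts in the 4 nude libraries and were at least 678-fold and at least 797-fold lower than in AR3_het. Aire had 2 counts over the nude libraries against 252 CPM in AR3_het, a log2 ratio of −10.18 (95% counting interval −13.23 to −8.33). Of 18 cortical TEC genes 14 fell and 2 rose, also when adjusted over the list alone (median −2.02, adjusted p = 4.23e-09). Of 20 medullary TEC genes 16 fell and 2 rose, also when adjusted over the list alone (median −5.13, adjusted p = 1.39e-11, lost with an estimated correlation at adjusted p = 0.0608). Of 14 post-Aire and cornified-like genes 11 fell and 1 rose (11 and 2 adjusted over the list alone, median −6.48, adjusted p = 9.36e-13). Of 16 tuft cell genes 14 fell and 1 rose (15 and 1 adjusted over the list alone, median −6.65, adjusted p = 1.59e-16). Of 22 Aire-dependent antigens 19 fell and 2, Mup5 and Mup4, rose, also when adjusted over the list alone (median −7.00, or −5.81 at bounds, adjusted p = 1.38e-17), and the call of Mup4 was lost with limma-voom. Of 16 keratinocyte genes 14 fell and 0 rose (15 fell adjusted over the list alone, median −4.64, adjusted p = 2.59e-11). Of 22 genes reported as Foxn1-dependent 16 fell and 1 rose (17 and 1 adjusted over the list alone, median −2.94, adjusted p = 5.74e-14).

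Presentation genes and thymocyte-supporting factors fell in nude. Of 16 class II genes 15 fell and 0 rose, also when adjusted over the list alone (median −5.39, adjusted p = 1.95e-13, lost with an estimated correlation at adjusted p = 0.0608). H2-Aa, a class II chain, fell from 6748 ± 1403 to 70.2 ± 27.5 CPM (−6.59, SE 0.50, adjusted p = 1.84e-06). Of 17 class I genes 11 fell and 2 rose, also when adjusted over the list alone (median −1.40, adjusted p = 5.3e-06, lost with an estimated correlation at adjusted p = 0.11), with Tap1 at 64.4 ± 13.1 against 366 ± 20.4 CPM (−2.51). Of 16 thymocyte-supporting genes 12 fell and 4 rose, also when adjusted over the list alone (median −2.60, adjusted p = 6.07e-08). Of 29 interferon response genes 16 fell and 2 rose, also when adjusted over the list alone (median −0.83, adjusted p = 0.0185), with Cxcl10 at −1.89. The interferon call was lost with an estimated correlation (adjusted p = 0.473) and without nude 3. Of 19 NF-kB genes 12 fell and 4 rose (14 and 4 adjusted over the list alone, median −0.71, adjusted p = 0.0439), among them Cd40, a receptor of medullary TEC (−6.53). That call was lost with an estimated correlation (adjusted p = 0.273), with the replicate block, and without AR3_mut 1 or nude 1. Of 22 cell cycle genes 17 fell and 1 rose (19 and 1 adjusted over the list alone, median −1.55, adjusted p = 0.00103, lost with an estimated correlation at adjusted p = 0.437), and Stmn1, a tubulin-binding protein of dividing cells, fell from 109 to 1.66 CPM (−6.05).

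Thymocyte, myeloid, endothelial and fibroblast lists moved in nude in the directions seen in AR3_mut. Of 26 thymocyte genes 25 fell and 0 rose (25 and 1 adjusted over the list alone, median −7.35, or −6.95 at bounds, adjusted p = 9.17e-27), and Cd8b1 had 0 counts and was at least 777-fold lower. Of 18 myeloid genes 14 fell and 1 rose (15 and 1 adjusted over the list alone, median −4.00, adjusted p = 7.36e-06, lost with an estimated correlation at adjusted p = 0.157). All 21 endothelial genes rose, also when adjusted over the list alone (median 3.34, adjusted p = 2.29e-14, lost with an estimated correlation at adjusted p = 0.0815), with Selp at 132 ± 24.3 CPM (6.51). The endothelial list took 0.184 to 0.383% of the counts in nude. Of 25 fibroblast and pericyte genes 18 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p = 1.02e-07, lost with an estimated correlation at adjusted p = 0.0991), and Dcn, a matrix proteoglycan of fibroblasts, rose from 125 ± 41.8 to 4396 ± 1638 CPM (5.14). Of 24 immediate-early genes 23 rose and 0 fell, also when adjusted over the list alone (median 2.24, adjusted p = 8.14e-13), and they took 2.91 to 4.21% of the counts. Of 28 Wnt and BMP genes 12 rose and 3 fell (14 and 4 adjusted over the list alone, median 0.77, adjusted p = 0.00103, lost with an estimated correlation at adjusted p = 0.103), with Bmp4 at 57.2 ± 7.64 CPM (4.14). Of 20 extracellular matrix genes 12 rose and 4 fell, also when adjusted over the list alone (median 1.34, adjusted p = 0.0141, lost with an estimated correlation at adjusted p = 0.0608). Igfbp5, which binds insulin-like growth factors, rose from 238 ± 49.7 to 7355 ± 3002 CPM (4.95). Lists of early thymus transcription factors (3 rose and 5 fell of 14, adjusted p = 0.34), progenitor-associated genes (6 and 6 of 20, adjusted p = 0.385), Notch (5 and 4 of 18, adjusted p = 0.948), and tight junctions and adhesion (5 and 6 of 21, adjusted p = 0.876) were not called. Adjusted over the list alone these counts were the same apart from 7 and 6 progenitor-associated genes.

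Ranked by fitted fold change, the genes named for their increase in nude began with Scgb2b27 and Scgb1b27. Scgb1b27 was at 13790 ± 23360 CPM (13.65, SE 2.84, adjusted p = 0.00344) and Prol1 at 14400 ± 20550 CPM (13.49, SE 2.09, adjusted p = 0.000606), so the SD exceeded the mean. Scgb2b27 (13.81), Mup5 (12.90) and Wfdc12 (9.85) were higher, and Pip, with 0 counts in AR3_het, was at least 2340-fold higher. That bound pools counts over each group, to which nude 1 gave the most (1670 CPM, against 24.7 to 237 CPM in the other nude libraries). The calls of Scgb1b27, Scgb2b27 and Pip were lost with limma-voom, and that of Pip also without AR3_het 1, 2 or 3. Bricd5 and C1rb had 2 counts each over the AR3_het libraries and were higher in nude, with log2 ratios of 10.02 (95% counting interval 8.17 to 13.07) and 9.94 (8.08 to 12.98). Ranked by fitted fold change, the genes named for their decrease were Tbata, Fezf2, Cd8b1 and Psmb11 and also H2-M2, Dntt, Calm4 and Rptn, with 0 counts in nude, at least 959-fold, at least 713-fold, at least 547-fold and at least 492-fold lower.

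Between nude and AR3_het, 6182 genes (47.9%) differed, 3059 higher and 3123 lower in nude, and 4688 of them by 2-fold or more. With library totals in place of TMM, 2145 of 7012 called genes were higher in nude. The authors' deposited table gave 7092 genes, of which 6073 were shared with the 6182, all with the same sign. Of 31 lists 22 were called, and 9 with an estimated correlation.

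The effects in AR3_mut and nude against the shared AR3_het libraries ran together, those in nude with strain and age included. Across 12912 genes their log2 fold changes correlated at Pearson r = 0.884 against 0.46 in simulated data without any effect, and genes are not independent replicates here. Their covariance was 4.475 against 0.097 in the simulated data, a difference of 4.378. Of the genes called, 2171 were higher in both against 649 for independent lists, 2167 were lower in both against 644, and 29 went in opposite directions. In the simulated data the overlap was 0, but without any effect few genes can be called. That value therefore does not show how much shared controls add to the overlap. No split of 3 controls leaves 2 libraries on each side, so part of the excess in shared calls may come from the shared controls.

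**Figure D3:**
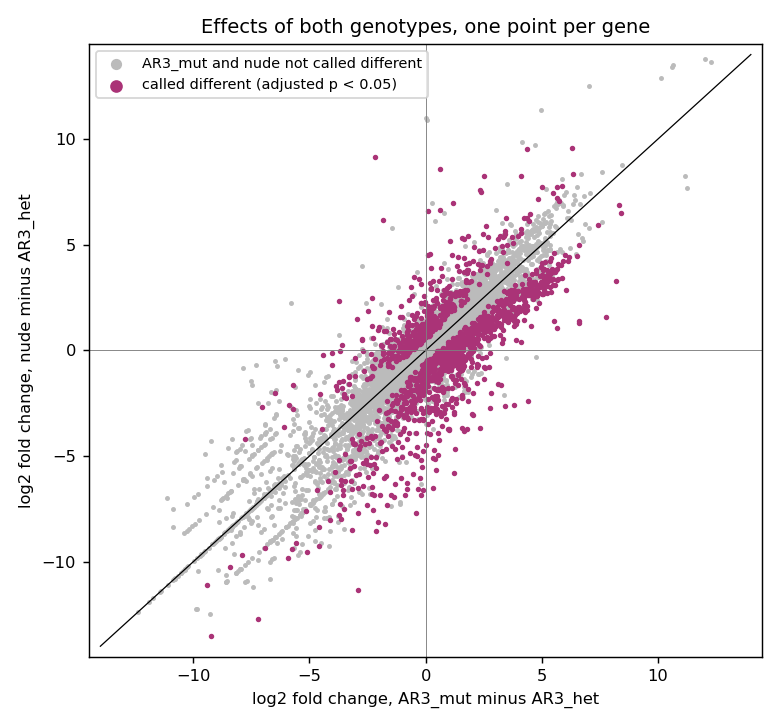
Log2 fold change of AR3_mut against AR3_het on the x axis and of nude against AR3_het on the y axis, 1 point per gene for 12912 genes, with a line of equal effects. Points in purple are the 1458 genes that differed between AR3_mut and nude, and the Pearson r across genes is 0.884.

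The comparison of AR3_mut with nude tests the difference between these effects directly, and strain and age change with it. Most endothelial and thymocyte-supporting genes were higher in AR3_mut. Of 21 endothelial genes 19 were higher in AR3_mut and 0 lower (20 and 0 adjusted over the list alone, median 1.88, adjusted p = 2.48e-26, lost with an estimated correlation at adjusted p = 0.0673). Plvap was at 1352 ± 143 CPM in AR3_mut and 327 ± 92.2 CPM in nude (SD, n = 3 and 4; 2.05, SE 0.22, adjusted p = 0.000539), and Vwf, the clotting protein of endothelium, at 358 against 66.8 CPM (2.42). Of 16 thymocyte-supporting genes 10 were higher and 1 lower (10 and 2 adjusted over the list alone, median 1.54, adjusted p = 1.9e-05), the list that also passed with an estimated correlation (adjusted p = 0.0482). Ccl25 was at 11.3 ± 4.15 against 3.18 ± 1.21 CPM (1.84, SE 0.33, adjusted p = 0.00541) and 4050 CPM in AR3_het. Vcam1, an adhesion molecule of stroma and activated endothelium, was at 89 against 25.1 CPM (1.83). Ccl19, a chemokine of medullary TEC and fibroblasts, was at 14 ± 14.9 CPM in AR3_mut, had 0 counts in nude and was at least 57.1-fold higher on counts pooled over each group, to which AR3_mut 1 (30.9 CPM) gave the most. Dll4 was at 163 ± 32.8 against 57 ± 28.7 CPM (1.52, SE 0.33, adjusted p = 0.0146), a call lost without AR3_mut 3 (adjusted p = 0.0503, the highest over 15 alternatives that began at 0.000422). Tbata was at 8.81 against 0.421 CPM (4.29), both far below AR3_het. Of 18 cortical TEC genes 8 were higher and 1 lower (9 and 4 adjusted over the list alone, median 0.94, adjusted p = 0.0213), and the call was lost with an estimated correlation (adjusted p = 0.202) and with the replicate block. Of 22 genes reported as Foxn1-dependent 7 were higher and 1 lower (8 and 1 adjusted over the list alone, median 0.92, adjusted p = 0.00331, lost with an estimated correlation at adjusted p = 0.202).

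Some presentation, interferon and Notch genes were also higher in AR3_mut than in nude. The endothelial list took a mean of 1.01% of the counts in AR3_mut and 0.286% in nude. Whether that difference carries these genes was not tested. Of 17 class I genes 9 were higher in AR3_mut and 1 lower (11 and 1 adjusted over the list alone, median 1.16, adjusted p = 2.71e-06, lost with an estimated correlation at adjusted p = 0.202). Tap1 was at 207 ± 37.6 against 64.4 ± 13.1 CPM (1.68, SE 0.19, adjusted p = 0.00057) and 366 CPM in AR3_het, and Nlrc5 at 23.1 against 3.19 CPM (2.82). H2-K1, a classical class I chain whose alleles differ between strains, was at 3519 ± 998 against 939 ± 264 CPM (1.91). Of 16 class II genes 6 were higher and 2 lower (11 and 3 adjusted over the list alone, median 1.62, adjusted p = 0.00331), a call lost with an estimated correlation (adjusted p = 0.527), with fry and without AR3_mut 1. Of 29 interferon response genes 11 were higher and 0 lower (17 and 0 adjusted over the list alone, median 0.80, adjusted p = 1.21e-09, lost with an estimated correlation at adjusted p = 0.202). Cxcl9, an interferon-induced chemokine, was at 24.4 ± 1.33 against 1.91 ± 1.13 CPM (3.60, SE 0.37, adjusted p = 0.00035) and 9.87 CPM in AR3_het. Cxcl10 was at 425 against 116 CPM (1.87) and Mx2 at 54.7 against 16.1 CPM (1.77). Of 18 Notch pathway genes 9 were higher and 0 lower, also when adjusted over the list alone (median 0.71, adjusted p = 2.71e-06, lost with an estimated correlation at adjusted p = 0.202), with the target Hey1 at 253 against 87.9 CPM (1.53) and Notch1 at 133 against 69.2 CPM (0.94). Of 18 myeloid genes 5 were higher and 0 lower, also when adjusted over the list alone (median 1.56, adjusted p = 0.00303, lost with fry and with an estimated correlation at adjusted p = 0.527). Of 19 NF-kB genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone, median 0.36, adjusted p = 0.0213), and the call was lost with an estimated correlation (adjusted p = 0.343) and without AR3_mut 2. Of 21 tight junction and adhesion genes 0 were higher and 2, Cgn and Epcam, were lower (0 and 1 adjusted over the list alone, median −0.46, adjusted p = 0.00331). Epcam was at 151 ± 74.5 CPM in AR3_mut and 373 ± 113 CPM in nude (−1.30, SE 0.38, adjusted p = 0.0461), with its call lost in 10 of 15 alternatives. The list's call was lost with an estimated correlation (adjusted p = 0.504), with fry and without AR3_mut 2.

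**Figure D4:**
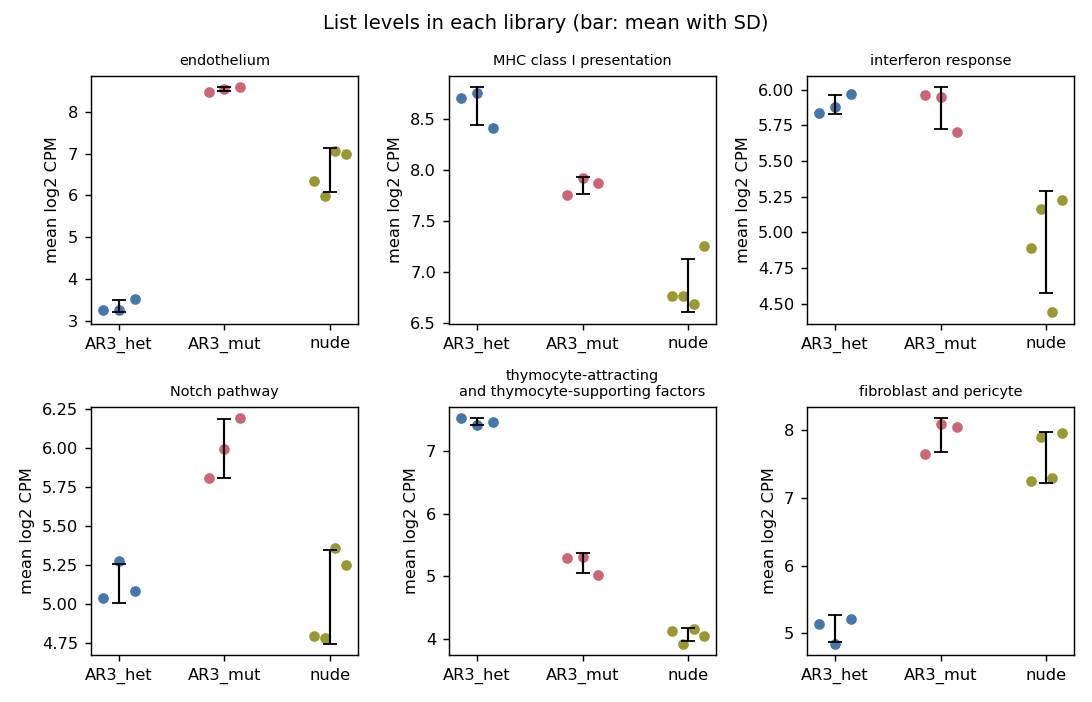
Mean log2 CPM of 6 gene lists in each library on the y axis, with a bar at the group mean and caps at 1 SD, for AR3_het (n = 3), AR3_mut (n = 3) and nude (n = 4). Endothelial genes lie highest in AR3_mut, and class I and interferon genes lie lowest in nude.

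Trim12a (a log2 ratio of 7.51, 95% counting interval 5.95 to 9.8, with 3 counts over the nude libraries), Mndal (5.93), Rnaset2b (5.55) and Ifi203 (5.46) were higher in AR3_mut, and Gbp2b (−5.98), C1s2 (−5.76) and C1rb (−5.16) were lower. Others were uneven between the libraries. Scgb3a1 (6.22), Crabp1 (6.09), BC048546 (5.50) and Ces1b (5.49) were higher in AR3_mut, and Obp2a (−11.32), Lcn11 (−7.97), Dnase1 (−6.48), BC037156 (−5.78) and Pde6a (a log2 ratio of −8.36, 95% counting interval −13.67 to −5.88) were lower. Of these, Scgb3a1, Crabp1, Obp2a, Lcn11, Dnase1 and BC037156 lost their calls with limma-voom, and those but Scgb3a1 also in other alternatives. Stmn1 was at 53.7 ± 17 against 1.66 ± 0.667 CPM (5.01, SE 0.33, adjusted p = 1.58e-05), with 109 CPM in AR3_het. Aldh1a1, a retinaldehyde dehydrogenase, was lower in AR3_mut (−2.03, adjusted p = 0.004), as was the Wnt antagonist gene Sfrp1 (−2.02, adjusted p = 0.00541). Lists of medullary TEC (3 higher and 0 lower of 20, adjusted p = 0.171), post-Aire TEC (1 and 0 of 14, adjusted p = 0.891), tuft cells (1 and 0 of 16, adjusted p = 0.768), Aire-dependent antigens (2 and 0 of 22, adjusted p = 0.958), keratinocytes (0 and 0 of 16, adjusted p = 0.735), thymocytes (2 and 0 of 26, adjusted p = 0.218), fibroblasts and pericytes (3 and 1 of 25, adjusted p = 0.257), immediate-early genes (2 and 0 of 24, adjusted p = 0.0868) and Wnt and BMP genes (2 and 3 of 28, adjusted p = 0.292) were not called. Neither were those of early thymus transcription factors (1 and 0 of 14, adjusted p = 0.834), progenitor-associated genes (1 and 2 of 20, adjusted p = 0.385), extracellular matrix (6 and 2 of 20, adjusted p = 0.305) and cell cycle (2 and 0 of 22, adjusted p = 0.454). Adjusted over the list alone the counts were the same for 7 of these lists and changed to 4 and 1 for medullary TEC, 6 and 3 for fibroblasts, 3 and 5 for Wnt and BMP, 2 and 0 for the transcription factors, 2 and 3 for progenitor-associated genes and 8 and 4 for matrix. Calls were gained for medullary TEC without AR3_mut 2, for immediate-early genes with the replicate block and without AR3_mut 2 or nude 4, for matrix with fry and for cell cycle without nude 2.

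Between AR3_mut and nude, 1458 genes (11.3%) differed, 979 higher and 479 lower in AR3_mut, and 1138 of them by 2-fold or more. The count depends on single libraries: it was 904 without AR3_mut 1 and 883 without nude 1, and 1993 without nude 3. It was 952 with these 2 groups fitted alone, without the AR3_het libraries. The authors' deposited table gave 1970 genes, of which 1438 were shared with the 1458, all with the same sign. Of 31 lists 13 were called, and 1 with an estimated correlation.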

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

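The tests of a lower share of thymic epithelial cells, of depth between AR3_mut and nude, and of a single gland-like source were chosen after their results were seen, and the others before. With 4 libraries, each nude value was checked against the other 3 with Dixon's ratio, and 17 of 124 sets of values passed its critical value. About 1 in 20 would pass by chance among independent sets of normal values. Most sets here are CPM of named genes, which are skewed, and several moved together in nude 1. The 17 can therefore not be set against that rate and only list values to look at. In nude 1, these were Scgb1b27 at 48700 CPM (434 to 5270 CPM in the other nude libraries), Scgb2b27 at 33300 CPM (286 to 4350), Prol1 at 45100 CPM (1520 to 5550), Obp2a at 19300 CPM (106 to 327), Wfdc12 at 10000 CPM (138 to 1100), Lcn11 at 5580 CPM (62.3 to 495), Pip at 1670 CPM (24.7 to 237), Scgb2b26 at 28.9 CPM (0.412 to 3.32) and Vcam1 at 32.2 CPM (22.5 to 23.1). In nude 3, Hes1 was at 372 CPM (236 to 241) and Hhex at 111 CPM (8.66 to 18). In nude 4, Tap1 was at 83.9 CPM (56.4 to 59.6), H2-Aa at 111 CPM (54.2 to 58.6), Ifi203 at 5.73 CPM (0.723 to 1.24), Mup4 at 1490 CPM (24.9 to 83.3), Spt1 at 7.78 CPM (0 to 0.553) and the mean log2 CPM of the class I list at 7.25 (6.68 to 6.76).

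For 4 named genes AR3_mut and nude moved in opposite directions from AR3_het, each past its test, and differed from each other. Mndal moved by 1.25 in AR3_mut and −4.68 in nude (difference 5.93), Ifi203 by 1.67 and −3.79 (5.46), BC048546 by 2.76 and −2.74 (5.50), and Cxcl9 by 1.31 and −2.29 (3.60). The nude side of each is confounded with strain and age.

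Endothelial and fibroblast genes were higher in AR3_mut and nude than in AR3_het. More endothelial and fibroblast cells, or their RNA, among the sorted cells may account for this: of 35 tested marker genes outside the fixed lists, 91.4% were higher in AR3_mut and 97.1% in nude. A lower share of epithelial cells that raises every other cell type alike would also raise thymocyte and myeloid genes. The thymocyte median was −5.75 in AR3_mut where the endothelial median was 5.26. The myeloid median was −2.32 in AR3_mut and −4 in nude, although the myeloid share of the counts reached 0.322% in AR3_mut 1 against 0.101 to 0.179% in AR3_het. These medians go against a rise of every other cell type alike. Thymocytes and myeloid cells in the tissue were not measured. Fewer of them there would lower these genes at any share of epithelial cells. The test therefore cannot exclude a lower share together with such losses, which stays open. Depth is argued against by thinning to the smallest library, where 21 of 21 endothelial genes were still higher in AR3_mut. The genotype itself, through the make-up of the thymic rudiment or expression within epithelial cells, stays open and untested, and the markers of the sort are not given.

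The genes called between AR3_mut and nude may reflect strain, age or the Foxn1 alleles, which cannot be told apart because they change together. The larger share of endothelial RNA in AR3_mut was not tested as a source of them. AR3_het was within 2-fold of AR3_mut for 39.7% of the 1458 genes, against 62.2% of all tested genes. Lower depth in AR3_mut is argued against as the whole cause, with 1074 genes called after thinning to the smallest library, 993 of them among the 1458. Over the 35 splits of these 7 libraries 1 called as many genes, the real one, with 952 genes against at most 431. For nude against AR3_het 1 of 35 did, with 6361 genes against at most 501. Both argue against chance, at the smallest share that 35 splits can give. That reading takes the libraries of a group as separate, which the labels do not say. For AR3_mut against AR3_het only 10 splits exist, too few for a share under 0.05, with 5454 genes in the real split, which 1 split reached, and at most 0 in the others.

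Among the nude libraries, 6 of 6 secretory protein genes (Scgb1b27, Scgb2b27, Prol1, Pip, Mup5 and Wfdc12) were highest in nude 1, the test made first. These 6 genes were picked from what prompted the test, Mup5 was nearly level in nude 4 (4620 and 4450 CPM), and Glycam1, Scgb3a1 and Mup4 were highest in nude 4, so the count is a description of these genes. RNA of 1 gland-like source in differing amounts could give this, and a source of fixed composition would hold the ratio of Scgb1b27 to Prol1 constant. In nude 1 to 4 that ratio was 1.08, 0.513, 0.949 and 0.08, so it differed 13.5 times, but without nude 4 it differed 2.1 times. Of the 10 pairs of these genes with over 100 counts in each nude library, 8 differed over 4 times, and 1 did so whichever library was left out, Mup5 to Prol1 (at least 4.66 times, median over pairs 2.15). That pair goes against a fixed composition, but Mup5 is in a multigene family, and over the pairs as a set the difference rests on nude 4, so a single source stays open. Several sources, or expression by epithelial cells of these genotypes, were not tested.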

How the results depend on the processing

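Library totals without TMM, the joint removal of AR3_mut 3 and nude 1, and the removal of genes above 0.5% of a library were chosen after seeing the data. The number of genes called stayed within 1.5 times in 23 of 23 alternatives for AR3_mut against AR3_het (3736 to 5994, and 4444 to 5695 with 1 library left out) and for nude against AR3_het (4359 to 7401, and 5169 to 6596). For AR3_mut against nude it did so in 17 of 23. It was 952 with the 2 groups fitted alone, 948 with the replicate block, 566 tested against a 1.5-fold change and 583 without AR3_mut 3 and nude 1. With 1 library left out it ran from 883 without nude 1 to 1993 without nude 3, and was 904 without AR3_mut 1. The cause was not tested, except that the 1.5-fold test asks for more and fewer libraries carry less information. Fewer libraries do not account for the rise without nude 3. Library totals moved the median of all genes to −0.331 and −0.406 against AR3_het, and 2066 of 5947 and 2145 of 7012 calls were then higher, where TMM gave 2741 of 5402 and 3059 of 6182. Foxn1 kept its direction and call against AR3_het in 18 of 18 alternatives (−7.98 to −7.60 in AR3_mut and −8.56 to −7.53 in nude). Its difference between AR3_mut and nude was not called in any of 17 and reversed in 1, to −0.13 after thinning, at counts near the floor. With an estimated correlation 14 lists were called in AR3_mut, 9 in nude and 1 between them, where the preset gave 20, 22 and 13. Over 13 alternatives the correlation of effects ran from 0.863 to 0.896 and the shared calls from 3345 to 4443. Replicate numbers did not pair the libraries, with correlations of −0.31 to 0.16 for equal numbers. Of the named genes, 58 of 66 kept their side of the threshold in AR3_mut, 28 of 32 in nude and 28 of 36 between them, over 15 alternatives, and 0 reversed. Depth limits what can be said of genes near 3 counts: thinning to the smallest library left 4227, 4676 and 1074 calls.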

Other observations

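The lists below were fixed before the data were examined, and no test in this part was chosen after its result was seen. Adipocyte genes were called against AR3_het, with 8 of 15 higher and 1 lower in AR3_mut (median 3.44, adjusted p = 0.00501) and 9 higher and 1 lower in nude (median 2.06, adjusted p = 0.0319), also when adjusted over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.473 and 0.57), and that of nude also without nude 3. Between AR3_mut and nude, 3 were higher and 0 lower (adjusted p = 0.218). Fabp4, which capillary endothelium also expresses, was at 4596 ± 879 CPM in AR3_mut and 336 ± 69.2 CPM in AR3_het (3.77). Muscle genes were called in nude, with 1 of 9 higher and 6 lower, also when adjusted over the list alone (median −4.82, or −4.64 at bounds, adjusted p = 0.021, lost with an estimated correlation at adjusted p = 0.193). In AR3_mut against AR3_het (1 higher and 5 lower, adjusted p = 0.153) they were called with fry and without AR3_mut 3 or AR3_het 3 only. They were not called in AR3_mut against nude (1 and 1, or 2 and 1 adjusted over the list alone, adjusted p = 0.15). Muscle antigens are also expressed by medullary TEC.

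Ciliated and B cell genes were called between AR3_mut and nude. Of 17 ciliated genes 4 were higher in AR3_mut and 0 lower (13 and 0 adjusted over the list alone, median 2.92, adjusted p = 0.00331). That call was lost with an estimated correlation (adjusted p = 0.616), with fry and without AR3_mut 1. Of 6 B cell genes 2 were higher and 0 lower (5 and 0 adjusted over the list alone, median 2.49, adjusted p = 0.00282, lost with an estimated correlation at adjusted p = 0.343). Against AR3_het, neither list was called in AR3_mut (ciliated 2 higher and 1 lower, 1 and 0 adjusted over the list alone, adjusted p = 0.609; B cell 3 and 1, adjusted p = 0.654) or in nude (1 and 2, adjusted p = 0.386; 1 and 3, adjusted p = 0.385).

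Secretory, parathyroid and thyroid, and neural lists were not called with all libraries. Between AR3_mut and nude, the secretory list was called without AR3_mut 2 or AR3_mut 3 and the neural list without AR3_mut 3. The secretory list took 2.72% of the counts in AR3_mut 1 and 0.289 and 0.432% in AR3_mut 2 and 3. Of 26 airway-like secretory genes 6 were higher and 5 lower in AR3_mut (adjusted p = 0.878), 4 and 11 in nude (adjusted p = 0.227), and 7 and 3 between AR3_mut and nude (11 and 3 adjusted over the list alone, adjusted p = 0.0892). Of 9 parathyroid and thyroid genes 4 were higher and 2 lower in AR3_mut (adjusted p = 0.639), 4 and 2 in nude (5 and 2 adjusted over the list alone, adjusted p = 0.948), and 0 and 1 between them (0 and 2 adjusted over the list alone, adjusted p = 0.184). This list took 1.91% of the counts in nude 3 and 0.0258 to 0.284% in the other nude libraries. Tg was at 17700 CPM in nude 3 and at 0.409 to 221 CPM in the other nude libraries. In AR3_mut against AR3_het, Calcb, a neuropeptide gene, was lower at 1.29 against 137.5 CPM (−6.48), and Calca had 3 counts, a log2 ratio of −6.63 (95% counting interval −8.91 to −5.08). Hhex was higher at 40.5 against 1.92 CPM (4.42), and Pth, the parathyroid hormone gene, was higher at 1184 ± 1094 against 31.2 CPM (5.24, adjusted p = 0.0212). Pth was uneven, at 2260, 1220 and 72.7 CPM in AR3_mut 1 to 3, and its call was lost in 5 of 15 alternatives, namely limma-voom and without AR3_mut 1 or any 1 AR3_het library. Of 8 neural and Schwann cell genes 2 were higher and 2 lower in AR3_mut (adjusted p = 0.99), 3 and 2 in nude (3 and 3 adjusted over the list alone, adjusted p = 0.664), and 0 and 1 between them (adjusted p = 0.218). Sox10, a transcription factor of glia and some gland epithelia, was at 3.15 CPM in AR3_het, 62.7 ± 48.5 CPM in AR3_mut (4.32) and 124 ± 14.1 CPM in nude (5.36). The erythroid gene Alas2 was at 6.0 CPM in AR3_het, 52.4 CPM in AR3_mut (3.11) and 41.6 CPM in nude (2.79).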
